A study of Mus musculus with 6 samples.

How the data were processed

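Expression was measured on 6 Illumina BeadChip arrays, 1 per sample, from biotin-labelled complementary RNA. Per the labels' protocols, follicular B cells were selected from spleen with an antibody to CD23, and the cells of each of 3 mice were split between mock treatment and TAT-CRE before 72 hours of culture. GenomeStudio 1.8 is named in the submitters' processing notes. The deposited table of processed values holds a linear intensity for 45281 probes on each array. The sorted values of the 6 columns differ by at most 2.1, so the authors' intensities had been quantile normalized before deposit, and each array's median lies between 161.4 and 161.5, well above 0, so background had not been subtracted. A second deposited table holds signals and detection p-values in 12 columns whose names match no sample's labels. None of those columns was used.

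Groups were taken from the sample titles, and the mouse from the number in the titles and source names. A design fixed before the data were examined called for background correction and filtering from control probes and detection p-values of the second table. Its columns could not be tied to samples by name, and matching them by their values was not tried. The authors' normalized intensities were used in place of that table. They received normexp background correction (offset 16), quantile normalization and log2 in limma 3.58.1 on R 4.3.3. Detection was replaced by a threshold per array, the 95th percentile of 1504 probes of olfactory and vomeronasal receptor genes, which B cells are taken not to express. Both replacements were chosen after the files were seen and before any call was counted. Probes above the threshold on at least 3 of 6 arrays were kept, 15701 in all.

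Probe names came from a table pairing probes with GEO's platform annotation, in which 34885 probes have 1 gene, 18 have several and 10378 have none. Entrez identifiers of 34807 probes matched a mouse RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table served for names, synonyms and neighbouring genes, and no coordinates are printed because the genome build behind the array annotation is not given in the sources used here. Each gene was represented by its probe of highest mean, giving 9942 genes. Of 3878 genes with several tested probes, 8 had probes called in both directions and 679 had some probes called and others not, so a gene's value is that of the probe used.

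TAT-CRE was compared with mock by lmFit and eBayes in limma, without the mouse in the model, two-sided, with Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05. Pairing comes from the labels, which give the same mouse to arrays of the same number. Deviations from the group means of the arrays of each mouse correlated across genes at 0.104, 0.0349 and 0.0356. A fit with the mouse as a block gave 873 higher and 887 lower genes, and 1529 genes were called in both fits. Where a probe was not above background on any array of a group, the mean log2 deposited intensity of the brighter group was set against the lowest intensity above background on each array of the other, and the ratio is given as "at least". Background correction would raise these ratios.

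Of 40 gene lists fixed before the data were examined, 36 had at least 5 genes tested. Each was tested with camera in limma (preset correlation 0.01, Benjamini-Hochberg over the lists), with an estimated correlation and with fry beside it. None of the 6 lists that passed held with an estimated correlation. Older gene names in the lists were first matched through synonyms in a way that gave some members the wrong gene. This was noticed after list results had been seen, and the matching was corrected so that an official symbol is never read as a synonym.

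The genes named follow a rule fixed before the data were examined: Yy1, the 12 largest differences in each direction among genes past the threshold that moved the same way in all 3 mice, up to 4 members of each list with the smallest p, and a fixed set of switching, plasma cell and chromatin loop genes. H2ac15, H2ac10, Bcat1, Gpt2, Dbt, Ivd, Echs1 and Rn28s1 were named after their values were seen. Alternatives covered the background correction, normalization, filter, mouse block, array weights, variance model, threshold, single probes, the authors' values on a log2 scale, list tests, and each array and each mouse left out.

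The procedure was tested on simulated data in which 200 of 9942 genes were changed. It recovered 7.46% of genes changed by 0.5 on the log2 scale, 70.1% of those changed by 1 and 95.5% of those changed by 2. Of its 122 calls, 7 were false. The simulated noise was independent between genes and of equal variance in both groups. In the real data 16.0% of tested genes were called, and the median SD per gene was 0.229 in mock and 0.144 in TAT-CRE. The simulated rates may therefore not hold for these arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Quantile normalization sets the arrays' distributions equal, so a change in total RNA per cell would not be seen.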

Results

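RNA was measured in mouse splenic follicular B cells, the mature recirculating B cells selected here by CD23, on Illumina bead arrays that give a brightness per probe. The cells came from 3 C57BL/6 mice whose Yy1 gene was floxed, that is, flanked by the short sites at which Cre recombinase cuts and rejoins DNA. Yy1 encodes a zinc finger transcription factor that binds many promoters and enhancers. The cells of each spleen were divided between a mock treatment and TAT-CRE, a Cre protein joined to a peptide that carries it into cells, and were then cultured for 72 hours with lipopolysaccharide and interleukin 4 in medium with 20% serum. This stimulus drives heavy chain class switching towards IgG1 and IgE in mouse B cells, and the stated purpose of the comparison was the part that Yy1 takes in switching. The design gave 3 mock and 3 TAT-CRE arrays, 1 of each per mouse.

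Of 9942 genes tested, 790 were higher and 796 lower in TAT-CRE than in mock cells, and the median difference over all genes was 0.02 on the log2 scale. Each array had between 39.9% and 44.5% of its probes above the background threshold. Log2 values correlated across genes with r between 0.991 and 0.992 among TAT-CRE arrays, between 0.976 and 0.985 among mock arrays, and between 0.964 and 0.975 across the groups. The first principal component held 55.4% of the variance and separated the groups, and the second held 20.1% and separated mock 1 from mock 2. The median SD per gene was 0.229 in mock and 0.144 in TAT-CRE. The number of arrays limits the precision of every value below.

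Yy1 itself was lower in the TAT-CRE cells of all 3 mice. Its probe read 434 ± 23.4 (SD, n = 3) in mock and 142 ± 9.86 in TAT-CRE cells on the deposited intensity scale, and it was not above background on any TAT-CRE array. The log2 difference was -2.80 (95% confidence interval -3.18 to -2.41, limma adjusted p = 6.42e-06). Taken against the background level, Yy1 was at least 2.49-fold lower on the deposited intensities, and the fitted size depends on the background correction. The labels do not say which part of Yy1 is floxed or where the probe lies, so whether the probe reads the deleted part is not known. The fall in every mouse goes with the labels wherever the probe lies. It does not show what remains of the transcript outside the probe. No array of TAT-CRE on cells without floxed Yy1 was analysed here, so the comparison holds the protein treatment and the loss of Yy1 together.

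**Figure D1:**
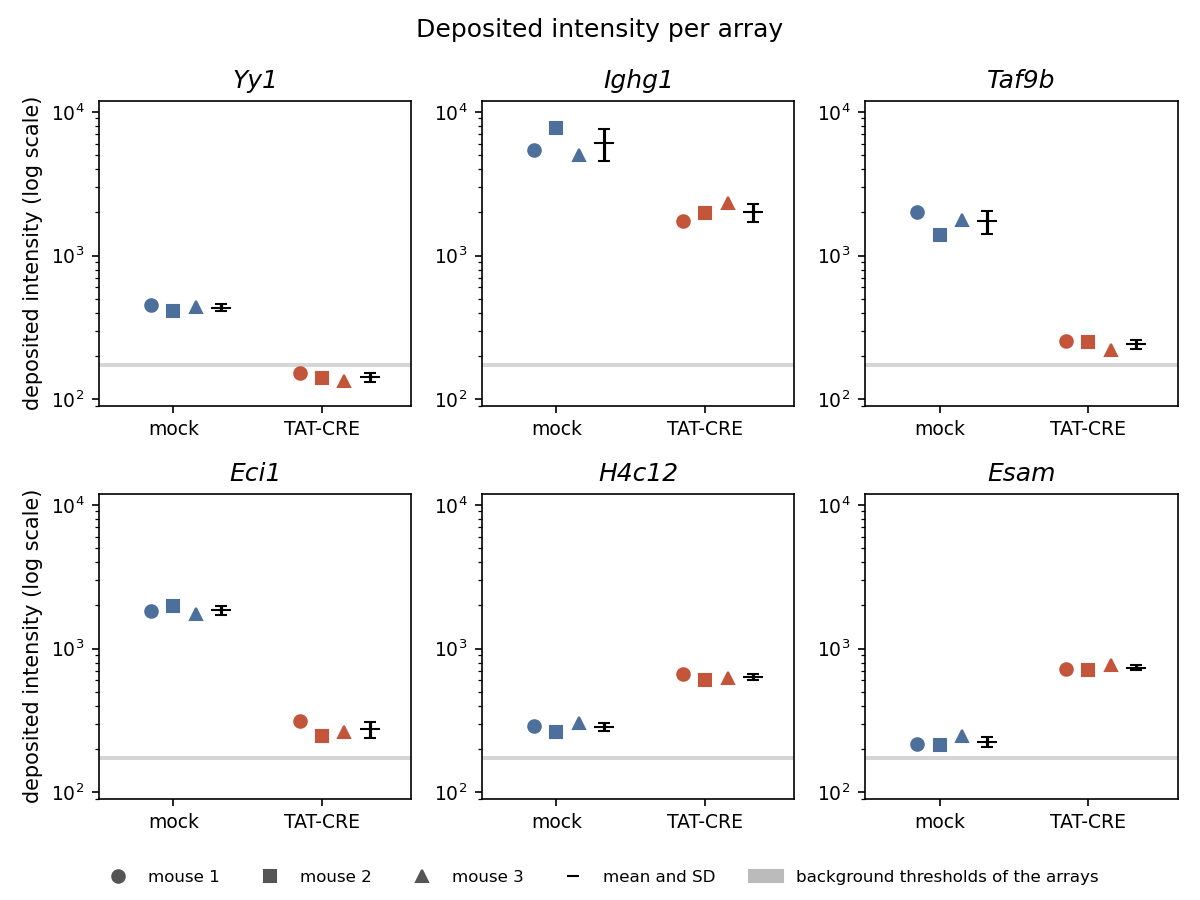
Deposited intensity, on a log axis, of 6 genes on each of the 6 arrays, with the symbol giving the mouse and the black bar the mean and SD of 3 arrays. The grey band spans the arrays' background thresholds; Yy1 lay below it on all 3 TAT-CRE arrays, while Ighg1, Taf9b and Eci1 were lower and H4c12 and Esam higher in TAT-CRE cells of every mouse.

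The largest falls were in genes with varied roles, several of them mitochondrial. Taf9b, a subunit of the general transcription factor TFIID, was 10.9-fold lower in TAT-CRE cells (log2 difference -3.45 ± 0.18, SE). Eci1, an isomerase in mitochondrial fatty acid oxidation, was 9.69-fold lower (-3.28 ± 0.18), and the mitochondrial protein gene Nipsnap1 7.96-fold lower (-2.99 ± 0.20). These sizes depend on the background correction, and over all alternatives the smallest differences were -2.75 for Taf9b, -2.68 for Eci1 and -2.23 for Nipsnap1. Other large falls were in the secretory pathway lectin Lman2l (-2.53), Cpox of haem synthesis (-2.44), the exchange factor Dock6 (-2.31), Hsd17b10 of mitochondrial isoleucine breakdown (-2.24), 2610035D17Rik (-2.55, above background on 1 of the 3 TAT-CRE arrays) and the stress-induced regulator Nupr1 (-2.33, above it on 2), and the sizes and order of these too depend on the background correction. The probes of the centrosomal gene Cdk5rap2 and the microtubule-associated Map7d3 were not above background on any TAT-CRE array, which makes each at least 2.03-fold lower on the deposited intensities. A second, dimmer Cdk5rap2 probe differed by -0.05. The other Lman2l probes differed by -2.86, which passed, and -0.50, which did not, and those of Cpox by -0.67, which passed, and -0.58, which did not.

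The largest rises were smaller than the largest falls. They were in Gm10125 (2.29 ± 0.20, SE), the adhesion molecule gene Esam (2.28 ± 0.16), the protease inhibitor Slpi (2.23 ± 0.35), the pseudogene Pisd-ps2 (2.05), the myosin light chain Mylpf (2.01), Gm7609 (between Mylpf and Hsd3b2 in size, adjusted p = 0.000110), the steroid dehydrogenase Hsd3b2 (1.99), the sphingosine kinase Sphk1 (1.95), Zxda (1.87), Erich5 (1.84), the lipid phosphatase Plpp3 (1.84) and Tspoap1 (1.79). The rule that named these rises and the largest falls above required the same direction in each of the 3 mice and an adjusted p under 0.05. Their limma adjusted p lay between 1.48e-06 and 0.00156. At least 2-fold changes were called for 158 higher and 196 lower genes, and at least 4-fold changes for 6 and 20. These counts and the sizes of the rises rest on background-corrected values. Over all alternatives the smallest differences were 2.06 for Gm10125, 1.64 for Esam and 1.84 for Slpi. Without TAT-CRE 1, 2 or 3 the calls fell to 399, 371 and 399 higher and to 389, 423 and 415 lower, and with no filter on dim probes to 370 and 391.

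Ighg1, the constant region gene to which these cells switch, fell by 1.62 on the log2 scale (SE 0.20, limma adjusted p = 0.000322), a 3.08-fold difference, from 12.52 ± 0.34 (SD, n = 3) to 10.89 ± 0.21. The paired differences were -1.69, -2.03 and -1.15 in mice 1, 2 and 3. Of the immunoglobulin list, 3 genes were tested, and the others rose: Jchain, which joins IgM pentamers, by 0.64 (adjusted p = 0.0305) and Vpreb3, a gene of the precursor B cell stage, by 1.12. All 3 also passed adjusted over the list alone. Which transcripts the Ighg1 probe reads is not given in the sources used here, so germline and switched transcripts were not separated. The Jchain call was lost without TAT-CRE 2, mock 3 or TAT-CRE 3 (adjusted p = 0.101, 0.102 and 0.141).

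In the list of class switch recombination and its DNA repair, 4 of 33 genes fell and none rose, with the same counts adjusted over the list alone. The list as a whole did not pass camera (adjusted p = 0.565). The 4 were Prkdc, the kinase of DNA end joining (-0.64), Ung, which removes uracil left by deamination (-0.76), Apex1, which nicks the resulting abasic sites (-0.61), and Nbn of the break-sensing complex (-0.69). The call was lost for Prkdc without TAT-CRE 1, 2 or 3 (adjusted p up to 0.0631) and for Ung without TAT-CRE 2 or mock 3 (0.0842 and 0.0504). Those of Apex1 and Nbn were lost without any array other than mock 2 (adjusted p up to 0.117 and 0.174). A second, dimmer Nbn probe differed by -0.08, so the fall of Nbn rests on 1 probe. The other Ung probes tested differed by -0.54 and -0.53 and did not pass (adjusted p over probes = 0.187 and 0.135). A second Prkdc probe differed by -0.59 and passed (adjusted p over probes = 0.0468). Ighm, Ighe, Ighg3 and Pax5 were not analysed here.

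At the probe used, none of 22 Igh enhancer binding and B lineage transcription factor genes changed in limma. This held over all genes and adjusted over the list alone. At an unadjusted p under 0.05, 2 were higher and 3 lower, and the camera adjusted p was 0.485. Foxo1 differed by -0.35 at the probe used, while a second, dimmer probe rose by 0.76 and passed (adjusted p over probes = 0.0206). Irf4 had a log2 difference of -0.55 (adjusted p = 0.0703). None of 15 cohesin and CTCF genes changed either, with 2 higher at an unadjusted p under 0.05 and a camera adjusted p of 0.405. Smc3 differed by 0.70 (adjusted p = 0.0669), Ctcf by 0.53 (adjusted p = 0.0669) and Rad21 by 0.61 (adjusted p = 0.248). Bcl6, the germinal centre repressor, differed by 0.54 (adjusted p = 0.0550), and the plasma cell regulators Xbp1 and Prdm1 by 0.16 and -0.14 (adjusted p = 0.509 and 0.692). With the mouse as a block, Smc3 and Bcl6 passed (adjusted p = 0.0260 and 0.0413), and over all alternatives their adjusted p ranged from 0.00277 to 0.329 and from 0.0222 to 0.233. Without mock 1, Irf4, Ctcf and Smc3 passed (adjusted p = 0.0481, 0.0193 and 0.0224), and without mock 2 Bcl6 did (0.0459). Rad21 differed by 0.93 without mock 1 and by 0.11 without mock 2, and over all alternatives its adjusted p ranged from 0.00594 to 0.853.

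Replication-dependent histone genes were the list that moved most. Of 43 tested, 25 rose and 2 fell (27 and 5 adjusted over the list alone), and the median log2 difference was 0.71. The camera adjusted p was 2.90e-07, and the adjusted p was 0.349 with an estimated correlation. H4c12 rose by 1.49, H3c1 by 1.42, H2ac18 by 1.27 and H3c6 by 1.16, each with SE between 0.15 and 0.16. The rises were 9 of 10 H4, 8 of 9 H2B and 5 of 9 H3 genes, while H2A genes had a median of -0.41, with 3 of 13 higher and 2 lower. Those that fell were H2ac15 (-0.76) and H2ac10 (-0.58). The H2ac15 call was lost without TAT-CRE 3 (adjusted p = 0.0526), and that of H2ac10 without TAT-CRE 1, mock 2, mock 3 or TAT-CRE 3 (up to 0.133). Histone genes of 1 family are close copies, so the change of any single one is uncertain.

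Cytosolic ribosomal protein genes also passed as a list, with 5 of 56 higher and none lower (4 higher adjusted over the list alone) and a median of 0.10. The camera adjusted p was 0.0430, against an adjusted p of 0.511 with an estimated correlation. Rplp0, of the ribosomal stalk, rose by 1.73, Rpl14 by 0.85, Rpl21 by 0.83 and Rpl24 by 0.70. The list's call was lost without mock 2, TAT-CRE 2 or TAT-CRE 3 (adjusted p = 0.113, 0.0719 and 0.0624), with cyclic loess (0.0542) and without Rplp0 (0.0808), the last tried after the result was seen. Ribosomal protein genes have many pseudogenes, so the named values are uncertain, and calls were lost for Rpl14 without TAT-CRE 1 or 3 (adjusted p up to 0.0694), for Rpl21 without TAT-CRE 2 or 3 (up to 0.0694) and for Rpl24 without TAT-CRE 1 (0.0567).

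Genes of 3 metabolic lists fell. Among serine, folate and amino acid genes, 8 of 25 fell and none rose (13 and 0 adjusted over the list alone; camera adjusted p = 2.40e-05, adjusted p = 0.151 with an estimated correlation). The largest falls there were Cth, which makes cysteine (-1.72 ± 0.19, SE), the mitochondrial folate dehydrogenase Aldh1l2 (-1.47 ± 0.16) and the neutral amino acid transporter Slc1a4 (-1.11 ± 0.16). Among glycolysis and hypoxia genes, 11 of 28 fell and 3 rose (13 and 3 adjusted over the list alone; camera adjusted p = 0.00106, adjusted p = 0.151 with an estimated correlation). They included the hypoxia-induced Ankrd37 (-1.82 ± 0.27), the phosphofructokinases Pfkp (-1.29 ± 0.21) and Pfkl (-0.94 ± 0.16) and the aldolase Aldoc (-0.99 ± 0.17). Of the cholesterol synthesis genes, 6 of 23 fell and none rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.000445, adjusted p = 0.151 with an estimated correlation), with lanosterol synthase Lss at -1.11, Nsdhl at -0.93 and the demethylase Cyp51 at -0.91. A dimmer probe of each of Aldh1l2, Pfkl and Lss did not pass (adjusted p over probes = 0.710, 0.743 and 0.999), while another of Aldh1l2 did, at -1.35.

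MYC targets and ribosome biogenesis genes fell as a list too, with 11 of 32 lower and none higher (15 and 0 adjusted over the list alone). The camera adjusted p was 2.67e-05, and the adjusted p was 0.151 with an estimated correlation. Myc itself fell by 0.98 (adjusted p = 0.0122), the nucleolar protein gene Nop56 by 1.19 and Polr1b, a subunit of RNA polymerase I, by 0.89. The Myc call was lost without TAT-CRE 2 (adjusted p = 0.0556).

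**Figure D2:**
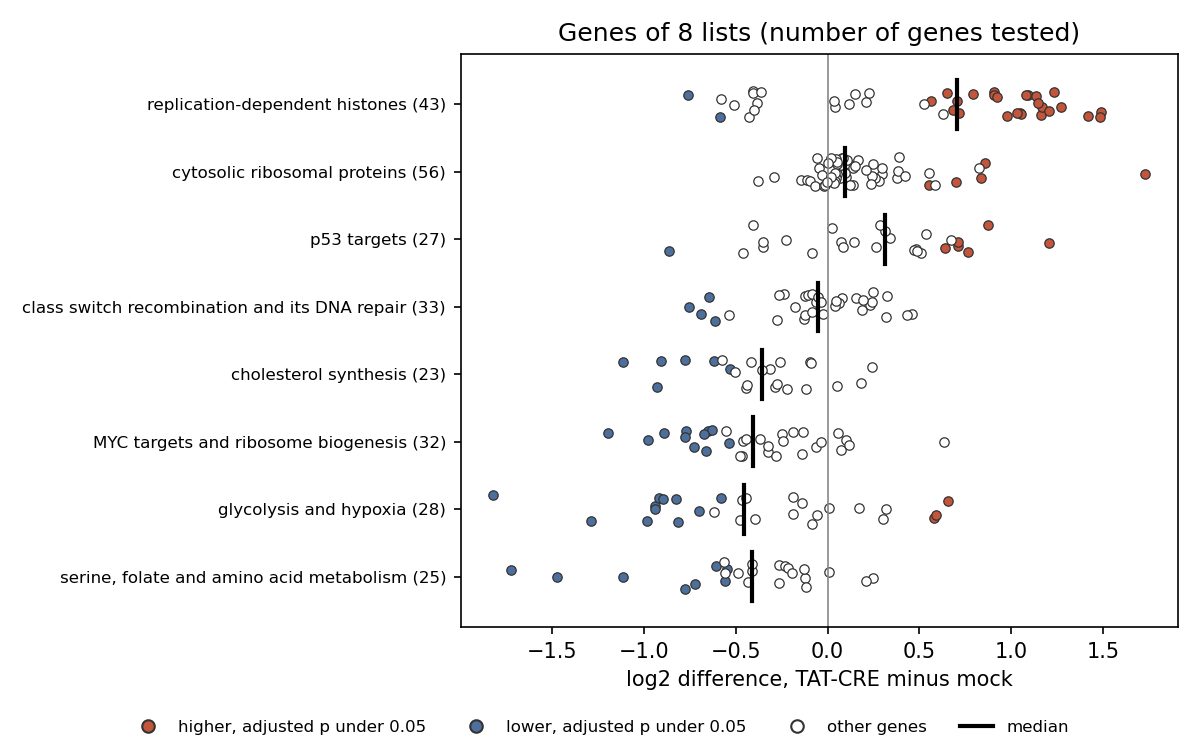
Log2 difference of each tested gene (dots, horizontal axis; positive is higher in TAT-CRE) in 8 gene lists, with filled dots for genes at adjusted p under 0.05 and a black bar for the list's median. The histone median lay at 0.71, while those of the MYC, glycolysis, amino acid and cholesterol lists lay at -0.40, -0.46, -0.41 and -0.36; open dots did not pass the test.

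Cell cycle lists did not pass. Of 42 DNA replication and S phase genes, 2 fell and none rose (2 and 0 adjusted over the list alone), namely Mcm5 (-0.79) and the thymidine kinase Tk1 (-0.86), and the list's median and mean lay at 0.03 and -0.05 (camera adjusted p = 0.644). Of 35 mitosis genes, 1 rose and none fell, over all genes and adjusted over the list alone (camera adjusted p = 0.644). The 1 was Mybl2 (0.88), whose other probes went both ways. One differed by -0.90 and passed, and the other by 0.50 and did not (adjusted p over probes = 0.00458 and 0.0761). The direction of Mybl2 is therefore uncertain. Among p53 targets, 6 of 27 rose and 1 fell (11 and 2 adjusted over the list alone), with a camera adjusted p of 0.0528, which was 0.0418 with the mouse as a block, 0.0348 without mock 1 and 0.349 with an estimated correlation, and ranged from 0.00452 to 0.620 over all alternatives. With fry the p53 list passed as higher (fry adjusted p = 0.00796). The repair nuclease gene Ercc5 rose by 1.20 and Ccng1 by 0.71, while the death receptor gene Tnfrsf10b fell by 0.86. The other 2 Ccng1 probes differed by -0.03 and 0.09, and the Tnfrsf10b call was lost without TAT-CRE 1 or TAT-CRE 3 (adjusted p = 0.0652 and 0.0974). The other Tnfrsf10b probes tested differed by between -0.16 and -0.04.

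Among apoptosis regulators 6 of 28 rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.644). The moved genes act both ways. Bcl2l11 (0.98), which promotes death, and Mcl1 (0.77), which opposes it, rose. The pro-death gene Bik, not above background on any TAT-CRE array, was at least 1.22-fold lower on the deposited intensities. Of the other Bcl2l11 probes tested, that at 1.09 passed, and those at 0.29 and 0.37 did not (adjusted p over probes = 0.375 and 0.258). In the list of B cell identity and antigen receptor signalling, 2 of 34 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.644). The Src family kinase gene Blk fell by 2.08 ± 0.20 (SE), the IgM Fc receptor gene Fcmr by 1.25 ± 0.17 and the kinase Prkcb by 0.95 ± 0.16, and Ralgps2 rose by 1.31 ± 0.16. The other Ralgps2 probes tested differed by 0.73, which passed, and by 0.46, 0.29 and 0.09, which did not. Of 30 Polycomb group genes, 5 fell and none rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.181), among them Phf19 (-1.32), L3mbtl2 (-1.02), Scmh1 (-0.89) and Pcgf1 (-0.87). Of 14 genes of the INO80 complex, a chromatin remodeller that contains YY1, 1 fell and none rose, with the same counts adjusted over the list alone (camera adjusted p = 0.181). None of 8 condensin genes changed in limma on either adjustment, with 2 higher at an unadjusted p under 0.05 (camera adjusted p = 0.471). With fry the condensin list passed as higher, and the Polycomb and INO80 lists as lower (fry adjusted p = 0.00796, 0.0308 and 0.0282). Of 20 plasma cell program genes 3 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.644).

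Markers of other cell types gave no shared direction. None of 7 T cell genes changed in limma, over all genes or adjusted over the list alone, and none had an unadjusted p under 0.05 (camera adjusted p = 0.863). Of 8 monocyte and macrophage genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.443). Among them Hmox1, a haem oxygenase that many stressed cells induce, was not above background on any TAT-CRE array and was at least 1.32-fold lower on the deposited intensities. Of 7 dendritic cell genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.668), with the transcription factor Batf3 at -1.79 and Siglech at 1.16. Natural killer, granulocyte, and erythroid and platelet lists had fewer than 5 genes tested, and in the first the perforin gene Prf1 rose by 1.51 while 2 genes fell. Of 10 marginal zone and B1 cell markers, 1 fell and none rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.107).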

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

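Alternatives that left out Rplp0, or that joined the estimated correlation with the mouse block, were chosen after the results were seen; the others were fixed before any call was counted. Of 99 genes named as changed besides Yy1 and Mybl2, 85 stayed past the threshold in each of 20 alternatives that tested them. None of the 99 reversed. Those alternatives used 1 probe per gene, so the test of single probes was not among them. Other probes of some of the 85 did not pass, such as 1 of Lss (adjusted p over probes = 0.999). Prdm1, not called, ranged from -0.30 to 0.0464 when single arrays were left out and was positive without TAT-CRE 3. With no filter on dim probes, which tests more genes, 370 genes were higher and 391 lower. With 1 array left out, 371 to 763 were higher and 389 to 814 lower, and without both arrays of 1 mouse, with the mouse as a block, 557 to 791 and 510 to 847. The higher lists numbered 1 with cyclic loess, 1 without Rplp0, 5 with fry, 0 with an estimated correlation and 0 when that was joined with the block; the lower lists numbered 8 with fry and 0 with either of the last. Leaving out 1 array gave 1 to 3 higher lists and 4 lower ones; leaving out mouse 2 or 3 gave 1 higher list. The cause was not tested. With the mouse as a block, 873 genes were higher and 887 lower; besides Smc3, Bcl6 and the p53 list it changed the call of no gene or list named in the report, though counts within lists moved. Yy1 lay between -2.95 and -1.51 in every setting that tested it and kept its call, and it was not tested where a probe had to be above the 99th percentile on all 6 arrays. Cyclic loess and median scaling ran on values the authors had already quantile normalized and so could move little. Detection p-values and the chip as a block were not run, since the columns that hold them were not tied to samples. Yy1 has 1 probe. Yy1 was -2.80 with normexp and -1.51 with no background correction.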

Other observations

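Among the tests below, those of S phase, shared histone sequence, dividing cells, Cre exposure, interleukin 4 and antibody-secreting cells were chosen after the result was seen, and the lists of activating transcription factor 4 targets and of acyl-CoA enzymes were drawn up after some of their relatives had been seen to fall.

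Signalling genes outside the switching list moved in both directions. Of 22 interleukin 4 response genes, 3 rose and 1 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.471), with metallothionein Mt1 at 1.25 and the signalling suppressor Socs3 at 1.01. Of 15 germinal centre genes, 4 rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.127). With fry the germinal centre list passed as higher (fry adjusted p = 0.0282). The ephrin Efnb1 lay at 1.22 and the migration receptor S1pr2 at 0.92. A second, dimmer S1pr2 probe did not pass (adjusted p over probes = 0.999). In the NF-kB and Toll-like receptor list 3 of 39 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.665), and the activation-induced factor Egr2 was lower by a log2 difference of -1.80. Among 45 interferon response genes, 2 rose and 4 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.161), with Oasl1 at -1.74, Isg15 at -1.12 and Ifi27 at 1.20. Of 25 antigen presentation genes 3 fell and none rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.161), H2-Ob (adjusted p = 0.00199) among them. Of 17 B cell trafficking genes, 2 rose and 2 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.850), and Klf2, which governs the exit of lymphocytes from tissue, rose by 0.90.

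None of the mitochondrial lists passed as a whole. Oxidative phosphorylation genes gave 4 higher and 4 lower of 70 (3 and 4 adjusted over the list alone; camera adjusted p = 0.902), with Uqcrc1 of complex III at -1.06 and Cox7a2 of complex IV at 1.17. Suclg2, a subunit of succinyl-CoA ligase, fell by 1.97 as the 1 changed gene of 16 in the tricarboxylic acid cycle list (1 adjusted over the list alone; camera adjusted p = 0.405). Of 71 mitochondrial ribosome genes, 2 rose and 9 fell (2 and 11 adjusted over the list alone; camera adjusted p = 0.405), with Mrps18b at -1.75 and Mrpl40 at -0.87. Few genes were called in the protein and RNA handling lists. Proteasome genes gave 2 lower of 31 (camera adjusted p = 0.245) and spliceosome genes 1 lower of 31 (camera adjusted p = 0.405). Heat shock genes gave 1 higher and 1 lower of 17 (camera adjusted p = 0.405). Counts were the same adjusted over each list alone. With fry the proteasome list passed as lower (fry adjusted p = 0.00796). Of 6 X inactivation and sex-linked genes, 1 fell (2 adjusted over the list alone; camera adjusted p = 0.404).

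The count of called genes was set against other divisions of the same arrays into 3 and 3. The division by treatment gave 1586 genes and 6 lists, and it was the 1 of 10 divisions to reach either count. The highest of the others gave 0 genes and 5 lists, and the division with 5 lists, like that by treatment, put the arrays of every mouse on opposite sides. With 10 divisions the share cannot fall below 0.05. Each of the other divisions mixed mock and TAT-CRE arrays on both sides, so the treatment difference added to their spread. Their counts therefore do not show what arrays without a treatment difference would give.

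In the unfolded protein response list 7 of 29 genes fell and 2 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.123), and the lowest were Atf3 (-1.56), Trib3 (-1.38), Atf4 (-1.17) and Chac1 (-1.12), which belong to the activating transcription factor 4 branch. With fry the unfolded protein response list passed as lower (fry adjusted p = 0.0263). A hypothesis is that targets of activating transcription factor 4 fell more widely. Of 24 further targets outside the fixed lists, 10 fell and 3 rose, with a mean log2 difference of -0.46 (camera p = 3.97e-05, and p = 0.0354 with an estimated correlation). Bcat1 lay at -1.76 and Gpt2 at -1.37. This is consistent with lower activity of the factor, which was not measured.

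Eci1 and Hsd17b10, among the lowest genes, led to a second hypothesis, that mitochondrial acyl-CoA breakdown fell as a group. Of 35 other genes of that pathway, 10 fell and 1 rose, with a mean of -0.22 (camera p = 0.0334, but p = 0.0696 with an estimated correlation). Dbt lay at -1.74, Ivd at -1.51 and Echs1 at -1.43. Another hypothesis was that genes rise beside genes that fall. Neighbours were taken among the 9934 tested genes placed in the RefSeq table of assembly GRCm38.p6. Untested genes between them were skipped, and distance was not limited. In that order 114 higher genes neighboured a lower one, against a mean of 119 in 10000 permutations (one-sided permutation p = 0.730). The hypothesis was not borne out for such neighbours, and directly adjacent genes were not tested apart.

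Histone genes had list medians of 0.74, 0.77 and 0.71 in the 3 mice, though the list did not pass with an estimated correlation (adjusted p = 0.349). More cells in S phase would raise DNA replication genes as well, but the highest of their medians in the 3 mice was 0.0576, below a bound of 0.353 set at 0.5 of the histone median, and over genes the median's 95% bootstrap interval was -0.09 to 0.11. That interval resamples genes, taken as independent, on the same arrays, so it holds no spread between mice. The same limit applies to the bootstrap intervals below. One sequence shared by the probes would put the histone rises in 1 family, but 4 of the 5 families held at least 2 of them. More RNA without a poly(A) tail in the TAT-CRE reactions stays open and cannot be told apart from a change in histone transcripts, since the 5 other such genes tested went both ways (highest median 0.187; Rn28s1 rose by 1.18), as does close copying within a family.

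The glycolysis, MYC, amino acid and cholesterol lists were lower with the preset correlation, but none passed with an estimated one (adjusted p = 0.151 for each), so the fall itself is not settled. A trend with intensity would make random lists of like intensity fall as far, which happened in at most 0.01% of draws, the smallest share that 10000 draws can give. Fewer dividing cells would lower mitosis genes, but the lowest of their medians in the 3 mice was 0.0163, above a bound of -0.179, and the bootstrap interval over genes was -0.09 to 0.19. Exposure to Cre protein or handling cannot be told apart from loss of Yy1, as 0 of the samples were TAT-CRE cells without floxed Yy1. Loss of Yy1 therefore may account for these lists but was not tested apart from that exposure.

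Ighg1 was lower in each mouse. Fewer antibody-secreting cells would lower Jchain as well, but Jchain was higher in every mouse, by at least 0.335 and up to 1.09 on the log2 scale. That rests on 1 gene, whose call was lost without TAT-CRE 2, mock 3 or TAT-CRE 3. The plasma cell program list had medians of 0.23, -0.17 and 0.10 in mice 1, 2 and 3. Fewer antibody-secreting cells therefore stay open as an explanation. A weaker response to interleukin 4 cannot be told apart from other reasons: the list's medians in the 3 mice lay between 0.0468 and 0.159, but its genes went both ways and the bootstrap interval was -0.17 to 0.32. A direct part of Yy1 in switching may underlie the fall and was not tested, nor was exposure to Cre.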
